A study of Mus musculus with 12 samples.

How the data were processed

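RNA of mouse neutrophils was measured on Illumina beadchips, where each probe sits on many beads and the brightness of those beads is averaged. The 12 arrays were grouped by the strain and the site given in the labels into C57BL/6 bone marrow, blood and peritoneal exudate and SV129/C57BL/6 bone marrow, with 3 arrays each, numbered as in the labels. Biotin-labelled cRNA was made from total RNA, per the labels' protocols. How the neutrophils were isolated, how pure they were and what stimulus gave the exudate were not given in the sources used here.

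The deposited signal table gave for each probe and array the mean bead intensity without normalization between arrays, per the file headers and the values. The same table held a detection p-value per probe and array, per the file headers, taken against negative control beads. It also held the number of beads and their standard error, other quantities deposited per probe and array, per the file headers. A second table held log2 values that the authors had normalized, with identical quantiles on all 12 arrays and a median of 5.46 in each column, and lumi and GenomeStudio are named, per the submitters' processing notes, without version or role. The background adjustment and any variance transformation behind these log2 values were not given in the sources used here. The value table of the series matrix was equal to it (largest difference 0). That table's columns of signed fold change, raw p-value and adjusted p-value, deposited by the authors, named neither the comparison nor the test. In the authors' deposited table the fold change correlated across probes at r = 0.992 with C57BL/6 bone marrow minus blood of the authors' log2 values (median absolute difference 0.0170), so that comparison was taken as the likely one. There, 4827 probes had an adjusted p under 0.05 in the authors' deposited table, 2156 with a positive and 2671 with a negative fold change. The authors' log2 values correlated at 0.9987 to 0.9989 per array, across probes, with the values used here.

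The comparisons, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where stated. Signals were background-corrected with limma's normexp method, with background mean and SD inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized on the log2 scale. Probes were kept where the detection p was under 0.05 on at least 3 of the 12 arrays, which left 20470 of 45281. Names came from the files and were updated through a table of current gene names: 29586 probes through the Entrez gene ID, 3940 through a current symbol and 3312 through a synonym, while 8443 kept the file's own name. A gene was represented by its kept probe with the highest mean over all arrays, which gave 14044 genes, 4374 of them with more than 1 kept probe. Probes of near-identical genes, such as the Bcl2a1, Stfa, Hspa1, globin and histone genes, may detect more than 1 copy.

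Group means were fitted with limma's lmFit and eBayes over all 12 arrays, with 8 residual degrees of freedom, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes. A gene was called under an adjusted p of 0.05. An exact test of 3 arrays against 3 cannot give a two-sided p below 0.1, so limma's p-values rest on its pooled spread. The difference between the step from marrow to blood and that from blood to exudate was tested as a contrast in the same fit. Overlaps of the calls of both steps were set against the product of the numbers of calls divided by the genes tested, and against 100 simulated sets of unchanged groups sharing the blood arrays.

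Lists of genes were 33, among them neutrophil identity, azurophil, specific and gelatinase granule proteins, cell cycle, haematopoietic progenitor genes, chemoattractant receptors, adhesion molecules, chemokines, cytokines, NF-kB targets and feedback genes, type I interferon response, pattern recognition, NADPH oxidase, Fc, complement and scavenger receptors, survival genes, cell death genes, lipid mediators, glycolysis, hypoxia-inducible genes, respiratory chain, ribosomal proteins, immediate early genes, heat shock and unfolded protein response, and markers of macrophages and monocytes, of MHC class II and dendritic cells, of B lymphocytes, of T and NK lymphocytes, of erythroid cells, of platelets and megakaryocytes, of eosinophils, basophils and mast cells, and of mesothelium and fibroblasts. The 32 with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Some genes stand on more than 1 list, such as Ngp, Cd177, Lcn2, Icam1 and Vegfa, and activated neutrophils can express some of the markers, Cd83 among them.

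Named genes were, in each comparison, the 8 highest and 8 lowest log2 differences among called genes with non-overlapping groups, detection on all arrays of at least 1 group and a symbol that is no clone, Riken, LOC or predicted name. To these came up to 4 members of each list with the largest absolute log2 difference, called members first, Rac1, Ly6g, S100a8, S100a9 and Csf3r throughout, and the genes of any counted group of 5 or fewer. Some genes and 1 gene list that entered the tests and counts are not reported here. The genes named as moving at both steps beyond these were chosen after their values were seen.

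The fit was tested on simulated data with the real means and spread, in which 200 of 14044 genes changed. Of 100 genes changed 2-fold 39% were recovered in blood against marrow, 29% in exudate against blood, 34% in exudate against marrow and 31% in the strain comparison, and of 100 changed 4-fold 86%, 88%, 84% and 83%. False calls made up 5.44%, 5.04%, 6.52% and 4.65% of the calls, and 0 recovered genes had the wrong sign. Of 21 simulated lists in each comparison the 1 shifted list was recovered and 0 of the others were called. The number of arrays limits the precision. Replicate differences were set against the bead error over 8000 probes with signals of 300 to 20000.

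Alternatives were no background correction, scaling to a common median, cyclic loess, an offset of 50, the authors' normalized values, the series matrix values, no filter, a detection p under 0.01 on all arrays of a group, the mean of a gene's probes, a trended and robust variance, only the groups compared, the replicate number as a block, array weights, SV129/C57BL/6 marrow as the reference, an adjusted p under 0.01, a 2-fold minimum, an estimated inter-gene correlation, and each array left out in turn. A beadchip block was planned and not run, since the files name no beadchip. Chosen after seeing the data were a block of the first and last 6 columns of the signal table, a fit without the 2 arrays that stood apart and list medians with genes at background at their bound. R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8) and Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3 were used.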

Results

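Gene expression was measured in mouse neutrophils (polymorphonuclear leukocytes), white blood cells that are made in the bone marrow, circulate in the blood and move into infected tissue. RNA of 12 samples was hybridised to Illumina beadchips with 45281 probes, each measured on a mean of 43.5 to 44.8 beads per array. The samples formed 4 groups of 3 arrays: bone marrow, blood and peritoneal exudate of C57BL/6 mice, and bone marrow of SV129/C57BL/6 mice that the labels call wild type for Rac1. Per the labels the mice were males of 6 to 8 weeks. Peritoneal exudate is fluid with cells collected from the abdominal cavity. The mean signal of an array lay between 484 and 616 intensity units, and 34.7% to 41.8% of probes lay above background, which covered 10788 to 12632 genes per array. Levels below are normalized log2 intensities, given as mean ± SD of 3 arrays, and 14044 genes were tested. Raw signals above 50000 units, close to the ceiling of the scanner, occurred for S100a8 on 12 arrays, Ltf and Ngp on 6, S100a9 and Hba-a1 on 5, Fpr2 on 4, Cd14 on 3, Cxcl10, Acod1, Fcer1g and Prg2 on 2, and Mpo, Camp, Igh-VJ558 and Arhgdib on 1, which limits the folds of these genes. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

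Correlations between arrays of 1 group lay between 0.922 and 0.995, and those between groups between 0.836 and 0.968. C57BL/6 bone marrow replicate 1 and exudate replicate 3 stood apart from their groups. The spread between the first and the other 2 marrow arrays was 11.5 and 11.3 times the bead error, against 4.17 times between those 2. For exudate replicate 3 it was 6.32 and 6.93 times, against 2.68 times. The closest pair, SV129/C57BL/6 bone marrow replicates 1 and 2, differed by 2.01 times the bead error, which does not show whether they came from separate RNA samples, and the arrays were counted as labelled.

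The comparison of blood with C57BL/6 bone marrow asked how neutrophils differ between the place of their production and the circulation. The purity of the blood preparations was not given in the sources used here, and neither a mixed preparation nor a wrong label is excluded. Mpo, the myeloperoxidase of azurophil granules, averaged 8.40 ± 0.29 in blood and 15.32 ± 0.24 in marrow (n = 3 each), a 121-fold difference (log2 difference -6.92, SE 0.45, limma adjusted p = 1.98e-06). Elane, which encodes neutrophil elastase, was 109-fold lower and Ctsg, cathepsin G, 108-fold lower. In the other direction, Prg4, a lubricin gene that resident peritoneal macrophages express, averaged 14.39 ± 0.94 in blood and lay at 4.79 ± 0.03 in marrow, above background on 0 of 3 marrow arrays, so it was at least 544-fold higher (adjusted p = 7.61e-06). Cd3g, a chain of the T cell receptor complex, lay at 13.13 ± 0.47 against 9.08 ± 0.92. For a gene above background on no array of a group, only a bound is given: the brighter group's mean was set against the higher of each dim array's own value and its lowest signal above background.

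In all, 4071 of the 14044 genes (29.0%) had an adjusted p under 0.05, of which 2319 were higher and 1752 lower in blood, and 1528 and 1194 of these changed at least 2-fold. The 8 largest rises among genes with non-overlapping groups were Prg4, Retnla, C4a, Ednrb, Ptgis, Saa3, Serpinb2 and C1qb. Non-overlap alone comes by chance in 10% of genes with 3 arrays against 3. Retnla, which encodes a secreted resistin-like protein, was 203-fold higher, the complement gene C4a 182-fold, the endothelin receptor gene Ednrb 181-fold, and the acute phase gene Saa3 109-fold. Ptgis, the prostacyclin synthase gene, was at least 78.7-fold higher and Serpinb2, a protease inhibitor gene, at least 64-fold. Among the falls, Prss34, a serine protease gene of basophils and mast cells, was 131-fold lower (adjusted p = 1.66e-08), Prg2, the eosinophil major basic protein gene, 81.4-fold, Fcnb, a ficolin gene, 44.8-fold, and the integrin gene Itgb2l 33.5-fold. Of the genes given with a fold in this comparison, Retnla, C4a, Saa3, C1qb, C1qc, Pf4 and Tlr1 lay above background on 2 of 3 marrow arrays, Ednrb and Cxcl1 on 1 of 3, and Ms4a3, Igll1 and Vpreb1 on 1 of 3 blood arrays.

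Of 11 measured azurophil granule genes, 8 fell and 1, Ctsc, rose (camera adjusted p = 5.22e-07, adjusted p = 0.156 with an estimated correlation), with Ms4a3 78.3-fold lower. Specific granule genes fell in 13 of 15 cases and rose in 0 (camera adjusted p = 8.87e-10, adjusted p = 0.156 with an estimated correlation): Orm1 was 28.7-fold, Cd177 22.5-fold, Olfm4 22.1-fold and Chil3 8.67-fold lower. On the gelatinase granule list 9 of 13 genes fell and 1, Hpse, rose (camera adjusted p = 0.000879, adjusted p = 0.385 with an estimated correlation). The falls were led by Mmp25 at 10.9-fold and the cathepsin inhibitor gene Stfa1 at 7.8-fold. The median level of this list was 9.14 on marrow replicate 1, 11.13 and 11.49 on the other marrow arrays and 8.13 to 8.94 on the blood arrays. The neutrophil identity list had 10 of 14 genes lower and 0 higher (camera adjusted p = 3.45e-06, adjusted p = 0.180 with an estimated correlation), among them Ngp at 7.68-fold and Mmp9 at 6.01-fold. S100a9, a subunit of calprotectin, was 2.19-fold lower (adjusted p = 0.000596), while its partner S100a8 had a log2 difference of -0.10 (adjusted p = 0.697). Csf3r, the G-CSF receptor gene, did not pass (log2 difference -0.59, adjusted p = 0.580). No kept probe carried the name Ly6g. Adjusted over the list alone, the counts of these 4 lists were the same.

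Proliferation genes were lower in blood: 25 of 33 cell cycle genes fell and 0 rose (camera adjusted p = 1.02e-12, adjusted p = 0.175 with an estimated correlation), with Cdca3 5.0-fold, the kinase gene Aurka 4.39-fold and Cdc20 4.01-fold lower. Of 16 haematopoietic progenitor genes 9 fell and 1, Spn, rose (camera adjusted p = 0.000114, adjusted p = 0.156 with an estimated correlation). Cebpe, a transcription factor gene of late granulocyte maturation, was 20.8-fold lower, Gata2 9.04-fold and the stem cell factor receptor gene Kit 8.02-fold. Both counts were the same when adjusted over the list alone. Ribosomal protein genes rose in 24 of 60 cases and fell in 2 (camera adjusted p = 7.47e-06, adjusted p = 0.489 with an estimated correlation), for example Rps15 2.39-fold, whereas Rpl3l (5.8-fold) and Rps27a were lower. In a test adjusted over the list alone, 28 rose and 2 fell. In the respiratory chain list 1 of 35 rose (Ndufa9, 1.5-fold), 1 fell (Ndufb9, 1.71-fold) and neither passed when adjusted over the list alone (camera adjusted p = 0.858).

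Markers of other cells moved with these groups on the same blood arrays. Of 17 T and NK lymphocyte markers 16 rose and 0 fell, and adjusted over the list alone 17 rose (camera adjusted p = 1.67e-12, adjusted p = 0.156 with an estimated correlation), with Cd3g 16.6-fold, Cd2 14.3-fold and the kinase gene Lck 11.2-fold higher. MHC class II and dendritic cell markers rose in 12 of 13 cases, 0 fell, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 3.53e-10, adjusted p = 0.156 with an estimated correlation); H2-Eb1 was 14-fold and Ciita 11.9-fold higher. Among 20 macrophage and monocyte markers 13 rose and 1, Ly6c1, fell (camera adjusted p = 2.50e-05, adjusted p = 0.309 with an estimated correlation). C1qb, a complement component gene, was 96.1-fold higher, C1qc 77.9-fold, Fn1, the fibronectin gene, 33.8-fold and Vsig4, a complement receptor gene of tissue macrophages, at least 34.6-fold. Of 16 B lymphocyte markers 10 rose, for example Blk 11.7-fold and Cd22 8.75-fold, and 2 fell (camera adjusted p = 0.00180, adjusted p = 0.470 with an estimated correlation). The 2 that fell, Igll1 (27-fold) and Vpreb1 (14.7-fold), encode the surrogate light chain of precursor B cells. Adjusted over the list alone, the macrophage and B lymphocyte counts were the same. Eosinophil, basophil and mast cell markers fell in 7 of 14 cases and rose in 2 (Mcpt4 and Cma1), adjusted over the list alone in 7 and 3, without a call for the list (camera adjusted p = 0.0692); the basophil protease gene Mcpt8 was at least 18.4-fold and Prg3 at least 14-fold lower. In the erythroid list 1 of 17 rose (Alas2, 7.19-fold), 0 fell and none passed when adjusted over the list alone (camera adjusted p = 0.427). In the platelet list 2 of 12 rose, Pf4 (34.8-fold) and F2rl2, and 1, Itga2b, fell, the same counts as adjusted over the list alone (camera adjusted p = 0.427). Of the 3 measured mesothelial and fibroblast genes, too few for the list test, Krt8 rose 2.01-fold, and Dcn (log2 difference 0.43) and Sparc (0.01) did not pass.

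Chemoattractant receptor genes fell in 7 of 15 cases and rose in 1, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.466 with an estimated correlation). Ltb4r1, the leukotriene B4 receptor gene, was 6.72-fold and the formyl peptide receptor gene Fpr2 6.41-fold lower. Chemokine genes rose in 8 of 18 cases and fell in 0 (camera adjusted p = 0.0351, adjusted p = 0.413 with an estimated correlation): the B cell attractant Cxcl13 was at least 23.5-fold and Cxcl1, a ligand of Cxcr2, 7.37-fold higher. Of 21 cytokine genes 6 fell and 0 rose (camera adjusted p = 0.00393, adjusted p = 0.156 with an estimated correlation), with the activin subunit gene Inhba 19.5-fold and Osm, oncostatin M, 4.34-fold lower. Glycolysis genes fell in 10 of 22 cases and rose in 3, Pfkl, Aldoc and Pdk1 (camera adjusted p = 0.00599, adjusted p = 0.309 with an estimated correlation), the falling genes including the hexokinase gene Hk3 (4.96-fold) and the glucose transporter gene Slc2a3 (4.92-fold). Pak1, a kinase downstream of Rac, was 3.15-fold lower against C57BL/6 marrow, but its log2 difference was 0.43 against SV129/C57BL/6 marrow. Rac1 itself did not pass (log2 difference -0.03, adjusted p = 0.917). For chemokines, cytokines and glycolysis the counts adjusted over the list alone were the same.

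Lists without a call are given with the counts of genes that rose and fell. They were adhesion molecules (6 and 0 of 18, with Itgb7 4.54-fold higher, camera adjusted p = 0.109), NF-kB targets and feedback genes (7 and 3 of 23, with Cd40 10.2-fold higher, camera adjusted p = 0.295) and survival genes (6 and 1 of 17, with Bcl2a1d 5.52-fold higher, camera adjusted p = 0.156). Pattern recognition genes split 2 and 8 of 27, with Trem1 7.72-fold lower and Tlr1 5.09-fold higher (camera adjusted p = 0.0999). NADPH oxidase genes split 0 and 3 of 8 (Ncf4 2.27-fold lower, camera adjusted p = 0.101), and Fc, complement and scavenger receptors 0 and 5 of 14 (C5ar1 3.91-fold lower, camera adjusted p = 0.0809). Hypoxia-inducible genes split 2 and 7 of 20 (Vegfa at least 6.89-fold lower, camera adjusted p = 0.105), and immediate early genes 4 and 2 of 21 (Klf2 3.04-fold higher, camera adjusted p = 0.490). Cell death genes split 3 and 2 of 24 (Fasl 4.67-fold higher, camera adjusted p = 0.789), and heat shock and unfolded protein response genes 4 and 2 of 21 (Pdia4 3.51-fold higher, camera adjusted p = 0.327). Of 28 type I interferon response genes 2 rose, Gbp3 and Ifi35, and 1, Cmpk2, fell (camera adjusted p = 0.643), and their median log2 difference was 0.23, which turned to -0.51 without marrow replicate 1. Lipid mediator genes (3 and 1 of 14) had a median of -0.21, a mean of 0.65 and an upward test result (camera adjusted p = 0.804), the median turning positive under median scaling, with Ltc4s at least 26.2-fold higher. Adjusted over the list alone, the counts that differed were those of NF-kB (8 and 4), survival (6 and 2), pattern recognition (2 and 10), cell death (2 and 2), interferon (1 and 0) and lipid mediators (4 and 1), and the other lists of this kind had the same counts.

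Of the 32 lists tested 16 were called in this comparison, 6 upward and 10 downward, with camera's preset correlation, and 0 with an estimated correlation (8 at an unadjusted p under 0.05). With each array scaled to a common median in place of quantile normalization, the median of all genes shifted by 0.19 and the share of higher calls was 74.3% against 57%. Without marrow replicate 1 the medians of cytokines and glycolysis moved from -0.69 and -0.56 to -1.07 and -0.84. The call of chemokines was lost without marrow replicate 1 (camera adjusted p = 0.118) or 2 (0.0530) or blood replicate 1 (0.157, median 0.20 against 0.62), and that of chemoattractant receptors without marrow replicate 2 (0.0603) or 3 (0.0713). Calls were gained without marrow replicate 1 for pattern recognition (camera adjusted p = 0.000443), NADPH oxidase (0.00317), Fc, complement and scavenger receptors (0.00106), eosinophil, basophil and mast cell markers (0.0378) and interferon genes (0.0485), each with a lower median in blood. Without blood replicate 1 pattern recognition (0.0235) and Fc receptors (0.0282) gained one, adhesion molecules without marrow replicate 3 (0.0372) or blood replicate 3 (0.0466), and the eosinophil list without blood replicate 3 (0.0373) or SV129/C57BL/6 replicate 3 (0.0419).

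**Figure D1:**
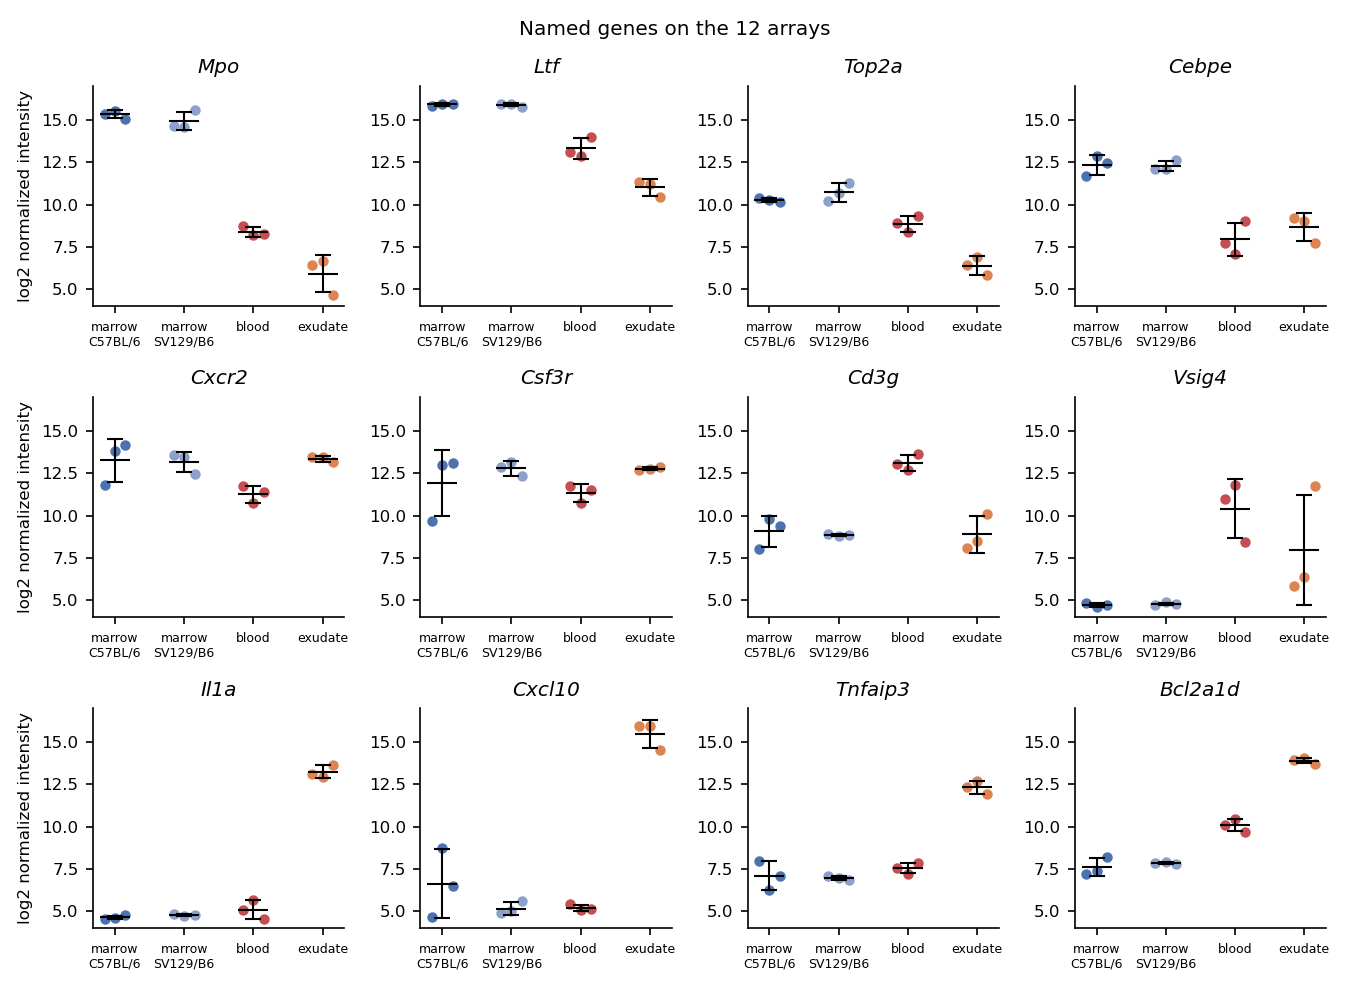
Normalized log2 intensity (y axis) of 12 genes in the 4 groups of arrays, where each point is an array, the bar is the group mean and the whiskers are 1 SD (n = 3). Mpo averaged 15.32 ± 0.24 in C57BL/6 bone marrow, 8.40 ± 0.29 in blood and 5.92 ± 1.10 in exudate, whereas Cxcl10 averaged 6.64 ± 2.05, 5.21 ± 0.18 and 15.46 ± 0.82.

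Exudate against blood asked how neutrophils change at the inflamed site. Cxcl10, an interferon-induced chemokine gene, averaged 15.46 ± 0.82 in exudate and 5.21 ± 0.18 in blood (n = 3 each), a 1223-fold difference (log2 difference 10.26, SE 0.76, limma adjusted p = 3.23e-06). Il1a, which encodes interleukin 1 alpha, was 279.6-fold higher (adjusted p = 1.48e-08), the neutrophil attractant gene Cxcl2 191-fold and Il1rn, the interleukin 1 receptor antagonist gene, 150.2-fold. Acod1, the gene of the itaconate-producing enzyme of activated myeloid cells, averaged 15.68 ± 0.12 against 7.08 ± 1.10 (389-fold). Thy1, a T cell surface protein gene, lay at 8.69 ± 1.14 against 13.04 ± 0.67, a 20.4-fold difference (adjusted p = 0.000143).

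Adjusted p lay under 0.05 for 4950 genes (35.2%), 1915 higher and 3035 lower in exudate, of which 1340 and 1757 changed at least 2-fold. Beside the genes above, the 8 largest rises held the cystine transporter gene Slc7a11 (115-fold), the chemerin-binding receptor gene Ccrl2 (92-fold) and the fatty acid receptor gene Gpr84 (84.7-fold). Among the falls, Alas2, the erythroid enzyme of haem synthesis, was 47.3-fold lower, Slc4a1, the red cell anion exchanger gene, at least 22.9-fold, the T cell receptor gene Trbv13-1 29.5-fold and Cd27, a co-stimulatory receptor gene, 20.8-fold. In this comparison Slc7a11, Cxcl9, Mcpt4, Tpsb2 and Ptges lay above background on 2 of 3 blood arrays and Cxcl10, Il1a and Ccl7 on 1 of 3, Mpo on 2 of 3 exudate arrays, and Trbv13-1 and Tk1 on 1 of 3.

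Cytokine genes rose in 19 of 21 cases and fell in 0 (camera adjusted p = 2.31e-15), with Tnf 38.4-fold and Csf1, the macrophage growth factor gene, 34.4-fold higher. Of 23 NF-kB targets and feedback genes 22 rose and 0 fell (camera adjusted p = 2.16e-20), among them the feedback inhibitor gene Tnfaip3 (27.1-fold), Marcksl1 (47.5-fold) and Gadd45b (26.8-fold). Survival genes rose in 10 of 17 cases and fell in 0 (camera adjusted p = 8.39e-06), for example the anti-apoptotic Bcl2 relatives Bcl2a1c (29.5-fold) and Bcl2a1d (14.1-fold) and the kinase gene Pim1 (13.6-fold). These 3 lists also held with an estimated correlation, at adjusted p = 0.00420, 0.00763 and 0.0107 in that order. In a test adjusted over the list alone, 20 cytokine, 23 NF-kB and 10 survival genes rose, and 1 survival gene fell.

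Among 28 type I interferon response genes 27 rose and 0 fell, and all 28 rose when adjusted over the list alone (camera adjusted p = 1.59e-15, adjusted p = 0.173 with an estimated correlation). The ubiquitin-like modifier gene Isg15 was 45.8-fold, Oasl1 28.2-fold, Cmpk2 25-fold and Usp18, which removes the Isg15 modifier, 22.5-fold higher. Chemokine genes rose in 12 of 18 cases and fell in 1 (Ccl5), also adjusted over the list alone (camera adjusted p = 7.74e-08, adjusted p = 0.0793 with an estimated correlation), with Cxcl9 40.1-fold and the monocyte attractant gene Ccl7 38.3-fold higher. Of 27 pattern recognition genes 19 rose and 1, Irak1, fell, or 20 and 1 adjusted over the list alone (camera adjusted p = 6.69e-11, adjusted p = 0.173 with an estimated correlation). Trem1, an amplifier of myeloid responses, was 34.9-fold, Tlr2, a receptor for bacterial lipoproteins, 32.3-fold and Cd14, a co-receptor for lipopolysaccharide, 31.3-fold higher. Immediate early genes rose in 14 of 21 cases and fell in 1 (Klf4), or 16 and 1 adjusted over the list alone (camera adjusted p = 1.23e-08, adjusted p = 0.101 with an estimated correlation), with Ier3 28.3-fold and Egr2 15.2-fold higher. Heat shock and unfolded protein response genes rose in 7 of 21 cases and fell in 1 (Hsp90ab1), also adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.101 with an estimated correlation), led by the chaperone genes Hspa1a (12.4-fold) and Hspa1b (5.48-fold).

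Several neutrophil lists were higher in exudate than in blood, where other cells' markers were high. Against marrow the gelatinase and identity lists had no call, so part of their rise may come from the blood arrays. On the gelatinase granule list 10 of 13 genes rose and 0 fell (camera adjusted p = 1.85e-05, 0.196 with an estimated correlation). Stfa2 was 14.6-fold, Arg2 14.2-fold and Adam8 11.4-fold higher. Neutrophil identity genes rose in 8 of 14 cases and fell in 1, Ngp (camera adjusted p = 0.000185, 0.196 with an estimated correlation), with Cxcr2 4.19-fold and Cd177 4.23-fold higher. Specific granule genes split, with 7 of 15 higher and 3, Ltf, Camp and Ngp, lower (camera adjusted p = 0.0103, 0.371 with an estimated correlation): Olfm4 was 19.5-fold and Orm1 8.2-fold higher, and Camp, the cathelicidin gene, 6.2-fold lower. In the azurophil list 1 of 11 rose (Cd63, 4.08-fold) and 2 fell (Mpo, 5.61-fold, and Arsb, 2.07-fold), with camera adjusted p = 0.591. S100a9 was 1.84-fold higher, and S100a8 (log2 difference 0.04), Csf3r (1.43) and Rac1 (-0.26) did not pass. Adjusted over the list alone, the counts of these 4 lists were the same. Chemoattractant receptors rose in 8 of 15 cases and fell in 2 (Cxcr3 and S1pr4), or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000169, 0.185 with an estimated correlation), with the platelet-activating factor receptor gene Ptafr 29.9-fold and the formyl peptide receptor gene Fpr1 24.2-fold higher. Of 14 Fc, complement and scavenger receptors 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 2.69e-06, 0.173 with an estimated correlation), among them Clec4n (83-fold) and the complement C5a receptor gene C5ar1 (13.7-fold).

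Cell cycle, ribosomal protein and respiratory chain genes were lower. All 27 called members of the 33 cell cycle genes fell, also adjusted over the list alone (camera adjusted p = 3.13e-11, 0.173 with an estimated correlation), with Kif22 7.35-fold, the thymidine kinase gene Tk1 7.31-fold and the cyclin gene Ccnb1 at least 4.09-fold lower. Ribosomal protein genes fell in 33 of 60 cases and rose in 1 (Rpl3l), or 38 and 1 adjusted over the list alone (camera adjusted p = 8.39e-06, 0.461 with an estimated correlation), for example Rpl13a (2.46-fold), without a call against marrow. Of 35 respiratory chain genes 20 fell and 0 rose, 24 falling when adjusted over the list alone (camera adjusted p = 0.000272, 0.346 with an estimated correlation), with Atp5o 2.19-fold and Ndufa4 1.98-fold lower. Glycolysis genes rose in 8 of 22 cases and fell in 2, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0230, adjusted p = 0.338 with an estimated correlation): the lactate transporter gene Slc16a3 was at least 5.7-fold and the glucose transporter gene Slc2a1 4.55-fold higher, and Pdk1 3.91-fold lower. Hypoxia-inducible genes rose in 6 of 20 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.0374, adjusted p = 0.173 with an estimated correlation), with the oxygen sensor gene Egln3 13.8-fold and Hif1a 7.43-fold higher. The median of that list, 0.32, turned to -0.048 under median scaling.

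Other cell markers moved with these groups. All 17 T and NK lymphocyte markers fell, also adjusted over the list alone (camera adjusted p = 6.12e-12, adjusted p = 0.130 with an estimated correlation), with Cd3g 18.8-fold and the cytotoxic granule gene Nkg7 16.6-fold lower. Of 16 B lymphocyte markers 7 fell and 0 rose, 10 falling when adjusted over the list alone (camera adjusted p = 0.00123, adjusted p = 0.371 with an estimated correlation), among them Vpreb3 (19.5-fold) and the IgE receptor gene Fcer2a (9.68-fold). MHC class II and dendritic cell markers fell in 6 of 13 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0318, adjusted p = 0.371 with an estimated correlation): H2-DMa was 3.81-fold lower and the activation marker gene Cd83 4.39-fold higher. Eosinophil, basophil and mast cell markers rose in 7 of 14 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.000180, adjusted p = 0.0793 with an estimated correlation). The members that rose most encode mast cell proteases, with Mcpt4 31.5-fold, Tpsb2 25-fold and Cpa3 10.5-fold higher and Tpsab1 at least 6.58-fold. Of 20 macrophage and monocyte markers only Cx3cr1 fell (5.11-fold) and 0 rose (camera adjusted p = 0.433). Vsig4, at 7.98 ± 3.25 in exudate, and C1qc, at 10.51 ± 2.28, did not pass, and exudate replicate 3 lay at 11.72 and 13.14 for these genes against means of 6.11 and 9.19 on the other 2 arrays. In the erythroid list 5 of 17 fell, among them Hba-a1 (9.53-fold), and 1 rose (camera adjusted p = 0.280), with the list median of -0.28 turning positive under cyclic loess. In the platelet list F2rl2 fell (1.81-fold), 0 of 12 rose and none passed when adjusted over the list alone (camera adjusted p = 0.454). Krt8 fell (1.66-fold) among the 3 mesothelial and fibroblast genes, and adjusted over the list alone Dcn rose too.

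The remaining lists had no call. Progenitor genes rose in 3 and fell in 2 of 16 cases, with Sox4 at least 4.83-fold lower and Kit 5.76-fold higher (camera adjusted p = 0.135). Adhesion molecules rose in 5 and fell in 4 of 18 cases, with Icam1 10.8-fold higher (camera adjusted p = 0.203). NADPH oxidase genes rose in 3 and fell in 1 of 8 cases (Cybb 3.44-fold higher, camera adjusted p = 0.272), and cell death genes in 7 and 5 of 24 (Fas 11.7-fold higher, camera adjusted p = 0.0691). Lipid mediator genes (3 up and 3 down of 14) had a median of 0.18, a mean of -0.20 and an upward test result (camera adjusted p = 0.591), the median turning negative under median scaling, with the prostaglandin E synthase gene Ptges 9.62-fold higher. In a test adjusted over the list alone, 5 lipid mediator genes rose and 4 fell, while the other 4 of these lists kept their counts.

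Of the 32 lists 22 were called, 16 upward and 6 downward, and 3 with an estimated correlation. Under median scaling the median of all genes shifted by -0.49, against -0.11 with quantile normalization, and 16.8% of calls were higher in exudate against 38.7%. Without exudate replicate 1, 3245 genes were called, and the medians of glycolysis and hypoxia genes moved from 0.51 and 0.32 to 0.32 and 0.16. The hypoxia call was lost without exudate replicate 2 (camera adjusted p = 0.0520, median 0.19) and the MHC class II call without blood replicate 2 (0.0727). The heat shock median of 0.21 moved to 0.39 without exudate replicate 2, 0.43 without exudate replicate 3 and 0.32 without blood replicate 2, and the eosinophil, basophil and mast cell median of 0.86 to 1.39 without exudate replicate 3 and 1.57 without blood replicate 3. Cell death genes gained a call without exudate replicate 3 (camera adjusted p = 0.0197) or blood replicate 1 (0.0327), and macrophage and monocyte markers without blood replicate 3 (0.0134, median -1.04 against -0.59).

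**Figure D2:**
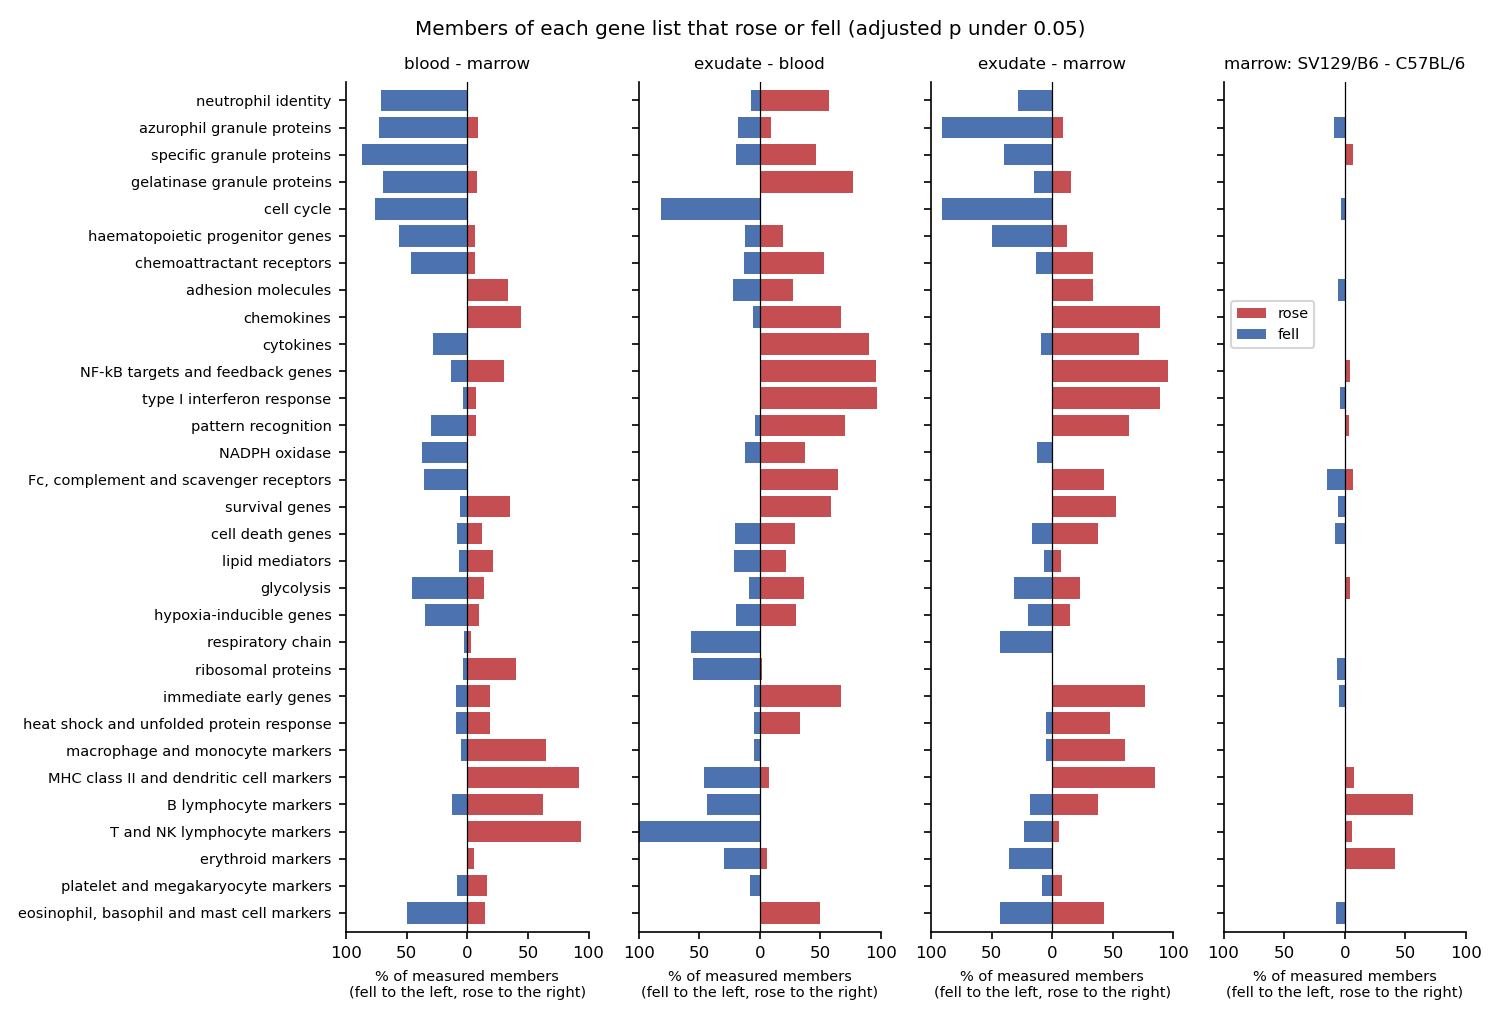
Percent of the measured members (x axis) of gene lists (y axis) that rose (bars to the right) or fell (bars to the left) in each of the 4 comparisons. All 17 T and NK lymphocyte markers fell between blood and exudate, where 27 of 28 interferon response genes rose.

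The path from marrow through blood to exudate was followed in 1 fit. The most positive difference between the steps, exudate minus blood less blood minus marrow, was that of Cxcl10, 11.69 on the log2 scale (SE 1.32, adjusted p = 6.63e-05), which did not pass in the first step and was above background on 2 of 3 marrow and 1 of 3 blood arrays. Among genes above background on at least 1 array of each group the most negative was that of Ednrb, -9.80 (SE 1.21, adjusted p = 0.000122). Prg4 rose in the first step and did not pass in the second, but its difference has no exact value, since it was above background on 0 of 3 marrow arrays. Cd3g rose and fell (-8.29). Olfm4 fell 22.1-fold between marrow and blood and rose 19.5-fold between blood and exudate (difference 8.75), and Trem1 fell and rose (8.08). The difference between steps passed for 4536 genes, 1800 of them positive and 2736 negative.

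Both steps called 2281 genes: 114 rose at both, 199 fell at both, 1314 rose and then fell, and 654 fell and then rose. Independent lists of the same sizes would share 316, 379, 501 and 239 genes. Of the cell cycle genes 24 fell at both steps, with the granule genes Camp, Ltf, Ngp and Mpo and the progenitor gene Sox4. Rising at both were the NF-kB targets Cd83, Icam1, Ikbke, Nfkb1, Nfkbie and Traf1, the survival genes Bcl2a1b, Bcl2a1c and Bcl2a1d, and the chemokine genes Ccl24, Ccl4, Cxcl1 and Cxcl16. Rising and then falling were 22 ribosomal protein genes and 16 T and NK lymphocyte markers. Falling and then rising were 8 neutrophil identity genes, among them Cd177, Cxcr2 and Lcn2, 8 gelatinase granule genes and 8 pattern recognition genes. The 3 blood arrays served both steps unsplit, so part of the excess of opposite moves may come from them or their neutrophil share. In 100 simulated sets without effects a mean of 0 genes was called at both, which cannot size that part. The steps' log2 differences correlated across genes at r = -0.472 against -0.499 in simulation, with a covariance of -0.515 against -0.0603, and genes are not independent replicates. Without blood replicate 2, 1485 genes were called at both steps, of which 127 fell at both and 378 fell and then rose. Without blood replicate 1, 69 rose at both, and without blood replicate 3, 419 fell and then rose. Under median scaling 2551 rose and then fell and 341 fell and then rose.

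**Figure D3:**
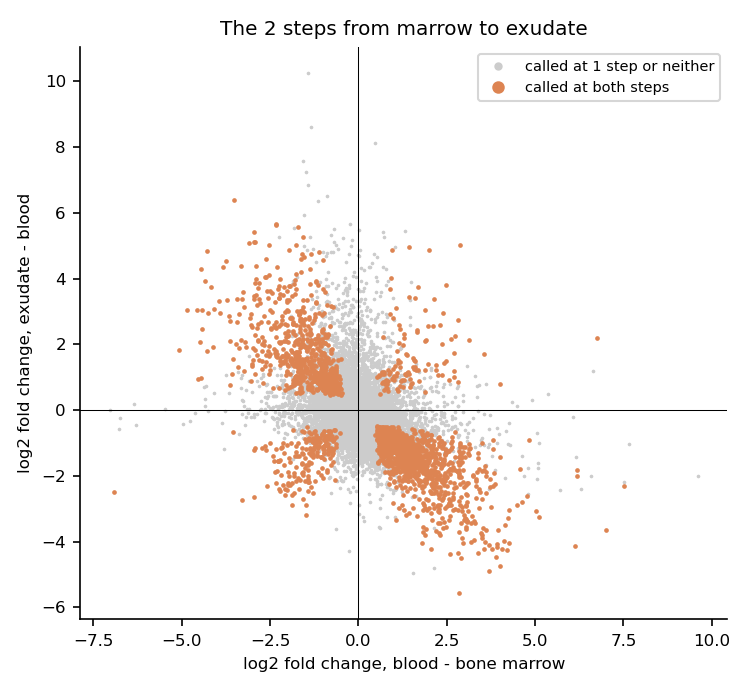
Log2 difference between blood and C57BL/6 bone marrow (x axis) against that between exudate and blood (y axis), where each point is a gene and the 2281 genes called at both steps are orange. The quadrants of opposite sign held 1314 and 654 of these genes.

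Peritoneal exudate was also set against C57BL/6 bone marrow directly, the ends of the path in the series title. Mpo had the largest fall, from 15.32 ± 0.24 in marrow to 5.92 ± 1.10 in exudate (n = 3 each), 679-fold (log2 difference -9.41, SE 0.45, limma adjusted p = 7.87e-08), followed by Elane (162-fold). Among the rises, Saa3 went from 6.02 ± 0.92 to 14.98 ± 0.47, 497-fold (adjusted p = 1.12e-06), and Cxcl10 rose 453-fold. Il1a, above background on 0 of 3 marrow arrays, was at least 244-fold higher. Bcl2a1d, an anti-apoptotic gene, rose 77.7-fold.

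In this comparison 4029 genes passed (28.7%), 1754 higher and 2275 lower in exudate, with 1311 and 1444 changed at least 2-fold. Further large rises were Cxcl1 (241-fold), Acod1 (154-fold), Serpinb2 (at least 145-fold), Prg4 (at least 135-fold) and the mast cell chymase gene Cma2 (at least 69.4-fold). Further large falls were Prss34 (132-fold), Ctsg (129-fold), Ms4a3 (at least 61.6-fold), Prg2 (72.2-fold), the immunoglobulin gene Igh-VJ558 (65-fold) and Camp (48.5-fold). Saa3, Cxcl10, Cd83, Nlrp3, Egr3, C1qb, Pf4 and Ptges lay above background on 2 of 3 marrow arrays and Cxcl1, Hspa1a, Mx2 and Cma1 on 1 of 3, Mpo and Elane on 2 of 3 exudate arrays, and Dcn on 2 of 3 exudate and 0 of 3 marrow arrays.

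Of 11 azurophil granule genes 10 fell and 1, Ctsc, rose (camera adjusted p = 3.22e-07, adjusted p = 0.104 with an estimated correlation). Specific granule genes fell in 6 of 15 cases and rose in 0 (camera adjusted p = 0.00103, adjusted p = 0.314 with an estimated correlation), with Ltf, lactoferrin, 29.8-fold and Ngp 17.1-fold lower. On the gelatinase granule list 2 of 13 genes rose and 2 fell (the arginase gene Arg2 4.03-fold higher, camera adjusted p = 0.272). Neutrophil identity genes fell in 4 of 14 cases (Cd177 5.32-fold) and rose in 0, without a call (camera adjusted p = 0.331), and their median of -0.06 turned positive under cyclic loess. S100a8 (-0.07), S100a9 (-0.25), Csf3r (0.84) and Rac1 (-0.29) did not pass. Of 33 cell cycle genes 30 fell and 0 rose, 32 falling when adjusted over the list alone (camera adjusted p = 8.88e-24, adjusted p = 0.0504 with an estimated correlation), with Kif22 27.1-fold and Cdca3 23.3-fold lower. Progenitor genes fell in 8 of 16 cases and rose in 2 (Myc and Etv6), or 9 and 3 adjusted over the list alone (camera adjusted p = 0.00880, adjusted p = 0.185 with an estimated correlation), with Sox4 at least 13.5-fold and Cebpe 12.8-fold lower. The granule and neutrophil identity counts were the same when adjusted over the list alone.

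The lists that held with an estimated correlation were NF-kB targets (22 of 23 rose, camera adjusted p = 9.01e-24, adjusted p = 0.00476 with an estimated correlation), survival genes (9 of 17, camera adjusted p = 4.50e-08, adjusted p = 0.00476 with an estimated correlation), chemokines (16 of 18, camera adjusted p = 1.64e-13, adjusted p = 0.0145 with an estimated correlation), cytokines (15 of 21, with Vegfa and Hgf lower, camera adjusted p = 3.62e-08, adjusted p = 0.0145 with an estimated correlation) and the heat shock and unfolded protein response (10 of 21, with Trib3 lower, camera adjusted p = 0.000131, adjusted p = 0.0339 with an estimated correlation). No member of the NF-kB, survival and chemokine lists fell. Members that rose were Tnfaip3 (37.1-fold), Cd83 (38.6-fold), Bcl2a1c (56.5-fold), Cxcl2 (64.5-fold), Il1rn (53.5-fold), Hspa1a (12.8-fold) and Hsph1 (4.29-fold), with Ccl7 at least 43.5-fold and the interleukin 10 gene Il10 at least 18.4-fold higher. Adjusted over the list alone, 23 NF-kB and 10 survival genes rose, 16 chemokine genes rose and 1 fell, and 16 cytokine genes rose and 2 fell, while the heat shock counts were the same.

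Type I interferon response genes rose in 25 of 28 cases and fell in 0, and all 28 rose when adjusted over the list alone (camera adjusted p = 1.18e-16, adjusted p = 0.185 with an estimated correlation), with Mx2 33.8-fold and Isg15 28-fold higher. Pattern recognition genes rose in 17 of 27 cases and fell in 0 (camera adjusted p = 5.05e-09, adjusted p = 0.217 with an estimated correlation), with Cd14 64.2-fold and the inflammasome gene Nlrp3 13.9-fold higher. Of 21 immediate early genes 16 rose and 0 fell (camera adjusted p = 4.82e-10, adjusted p = 0.0597 with an estimated correlation), among them Egr3 (29.9-fold) and Egr2 (27.3-fold). Fc, complement and scavenger receptors rose in 6 of 14 cases and fell in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000392, adjusted p = 0.314 with an estimated correlation), led by Clec4n (37.2-fold). Their median level was 7.88 on marrow replicate 1 against 10.11 and 10.09 on the other marrow arrays, and without that replicate their median difference fell from 1.48 to 0.76 (camera adjusted p = 0.0121). Adhesion molecules rose in 6 of 18 cases and fell in 0 (camera adjusted p = 0.00444, adjusted p = 0.217 with an estimated correlation), with Icam1 29.3-fold higher. Respiratory chain genes fell in 15 of 35 cases and rose in 0, 17 falling when adjusted over the list alone (camera adjusted p = 0.000114, adjusted p = 0.315 with an estimated correlation), for example Ndufb8 (2.15-fold). For the pattern recognition, immediate early and adhesion lists the counts adjusted over the list alone were the same.

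Markers of other cells differed here too. Of 13 MHC class II and dendritic cell markers 11 rose and 0 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.62e-08, adjusted p = 0.0629 with an estimated correlation), with H2-Aa 8.7-fold higher. Macrophage and monocyte markers rose in 12 of 20 cases and fell in 1 (Ly6c1), or 15 and 1 adjusted over the list alone (camera adjusted p = 0.000108, adjusted p = 0.284 with an estimated correlation), with C1qb 24.1-fold higher. Erythroid markers fell in 6 of 17 cases and rose in 0 (camera adjusted p = 0.0211, adjusted p = 0.318 with an estimated correlation), with Eraf at least 3.66-fold and Hba-a1 4.65-fold lower. Eosinophil, basophil and mast cell markers split, 6 of 14 higher and 6 lower (camera adjusted p = 0.331): of the mast cell genes, Mcpt4 was at least 49.3-fold and Cma1 47-fold higher. T and NK lymphocyte markers rose in 1 (Cd2) and fell in 4 of 17 cases (Nkg7 4.74-fold lower, camera adjusted p = 0.331). B lymphocyte markers rose in 6 and fell in 3 of 16 cases (camera adjusted p = 0.499), with Cd22 6.81-fold higher and Igll1 at least 21.5-fold lower, a median of -0.05 that turned positive under cyclic loess, a mean of -0.25 and an upward test result. The platelet list (1 up and 1 down of 12, camera adjusted p = 0.783, Pf4 17.5-fold higher) had a median of -0.28, a mean of 0.16 and an upward test result. Dcn, the decorin gene, was at least 2.06-fold higher among the 3 mesothelial and fibroblast genes. The counts of the last 6 lists were the same when adjusted over the list alone.

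No call was made for the other lists. Chemoattractant receptors rose in 5 and fell in 2 of 15 cases, or 7 and 3 adjusted over the list alone (S1pr4 6.19-fold lower, camera adjusted p = 0.0972). Glycolysis genes split 5 and 7 of 22 (camera adjusted p = 0.499), adjusted over the list alone 6 and 7. Hypoxia-inducible genes split 3 and 4 of 20 (camera adjusted p = 0.585), adjusted over the list alone 4 and 4, with Hif1a 5.49-fold higher. Cell death genes split 9 and 4 of 24 (Casp4 8.73-fold higher, camera adjusted p = 0.106), also adjusted over the list alone. In the lipid mediator list Ptges rose (7.11-fold) and 1 of 14, Alox5ap, fell, 0 when adjusted over the list alone (camera adjusted p = 0.499). Pak1, 2.04-fold lower here, had a log2 difference of 1.06 against SV129/C57BL/6 marrow. In the NADPH oxidase list 1 of 8 fell (the proton channel gene Hvcn1, 3.03-fold, camera adjusted p = 0.544), also adjusted over the list alone. Of 60 ribosomal protein genes 0 rose and 0 fell in limma (0 and 2 at an unadjusted p under 0.05), also adjusted over the list alone (camera adjusted p = 0.579), and their median of -0.07 turned positive under median scaling and to 0.25 under cyclic loess.

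Camera called 18 of 32 lists, 12 upward and 6 downward, and 5 with an estimated correlation. With only the arrays of these 2 groups in the fit 2170 genes were called. Under median scaling the median of all genes shifted by -0.19 and 30.4% of calls were higher in exudate against 43.5%. The adhesion call was lost without marrow replicate 1 (camera adjusted p = 0.0672, median 0.12 against 0.32), and its median was 0.61 and 0.60 without replicates 2 and 3. Erythroid markers lost theirs without marrow replicate 3 (0.0838, median -0.50 against -1.01) or exudate replicate 3 (0.0679), and progenitor genes without exudate replicate 3 (0.0613). The specific granule median of -1.12 moved to -0.57 without marrow replicate 2. Calls were gained by NADPH oxidase without marrow replicate 1 (camera adjusted p = 0.0459), chemoattractant receptors without replicate 2 (0.0433) or 3 (0.0316) of that group, cell death genes without its replicate 2 (0.0185), and, without exudate replicate 3, by cell death (0.0309), ribosomal protein (0.0479) and T and NK genes (0.0460).

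**Figure D4:**
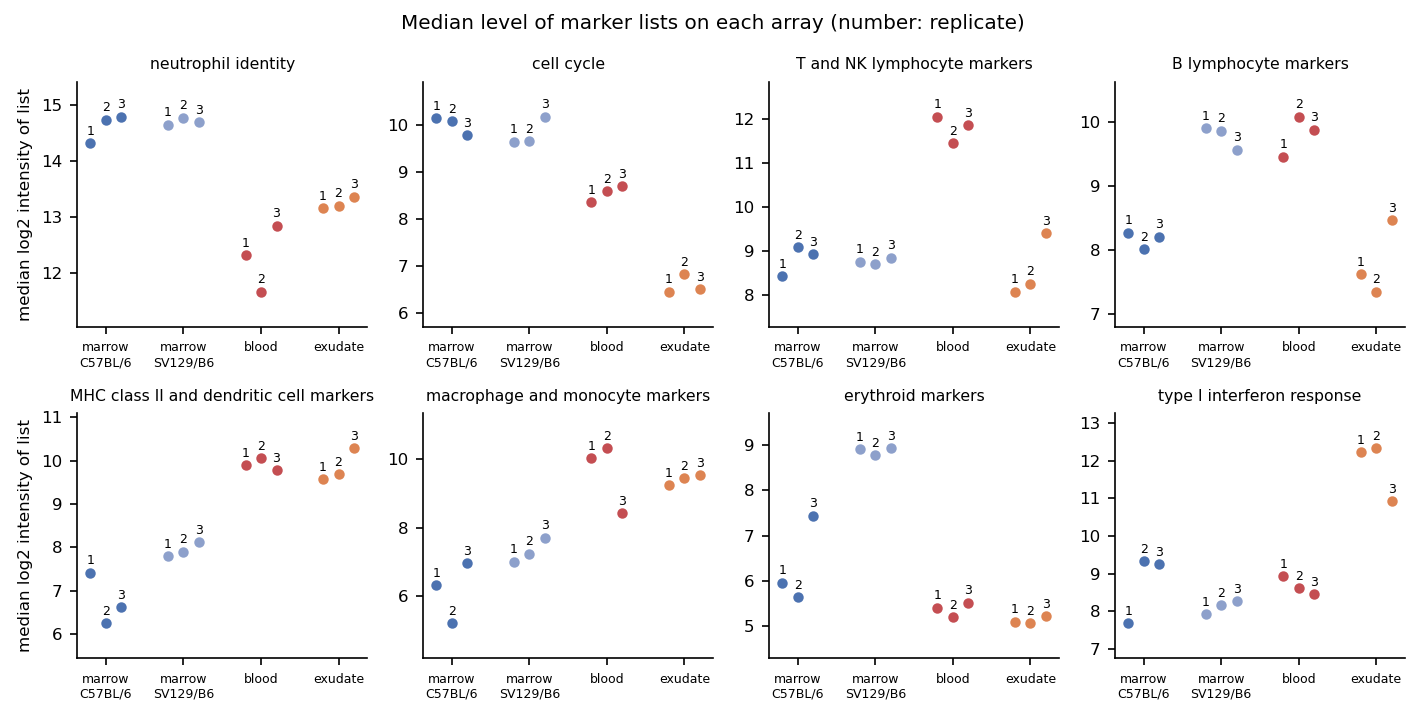
Median normalized log2 intensity (y axis, with its own scale in each panel) of 8 gene lists on each of the 12 arrays (x axis, by group), where each point is an array and the numbers are the replicates. The median of the T and NK lymphocyte list lay between 11.44 and 12.05 on the blood arrays and between 8.06 and 9.40 on the exudate arrays.

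SV129/C57BL/6 was compared with C57BL/6 bone marrow to ask how far marrow neutrophils differ between these backgrounds. Rac1, the small GTPase gene named in the sample titles, lay at 9.26 ± 0.19 and 9.05 ± 0.17 (log2 difference 0.21, limma adjusted p = 0.677) and did not pass. Fcer1g, the Fc receptor gamma chain, fell most, from 15.09 ± 0.55 in C57BL/6 to 4.59 ± 0.13 in SV129/C57BL/6 marrow (n = 3 each). There 0 of 3 arrays were above background, so it fell at least 881-fold (adjusted p = 6.72e-09). Rnase2a, an eosinophil-associated ribonuclease gene, rose from 5.30 ± 0.14 to 10.08 ± 0.01, 27.4-fold (log2 difference 4.78, SE 0.17, adjusted p = 9.50e-09). The kinase gene Fgr was 22.1-fold and the globin Hbb-b2, at background in all C57BL/6 groups, at least 16.6-fold higher. Its strain variants were untested.

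Fewer genes passed than between sites: 598 (4.26%), 383 higher and 215 lower in SV129/C57BL/6 marrow, with 343 and 187 changed at least 2-fold. Other large rises were Slc9a3r2 (20.1-fold), Eraf (17.2-fold), Cstdc5 (17-fold), Tmem45a2 (12-fold) and Ighv1-84 (at least 9.24-fold). Other large falls were Olfml2b (at least 51.3-fold), Casp4, an inflammatory caspase gene (at least 34-fold), Cd300ld (at least 35.8-fold), the mitotic kinase gene Plk1 (at least 27.9-fold), Casp9 (29.5-fold), Ctsc, which activates granule proteases (26.9-fold), and Arrdc3 (20.3-fold). Rnase2a and Cstdc5 lay above background on 2 of 3 and Nod2 on 1 of 3 C57BL/6 arrays, and Ctsc and Arrdc3 on 2 of 3 and Casp9 on 1 of 3 SV129/C57BL/6 arrays. Another probe of Casp9 and another of Itga4 (at least 3.68-fold lower) were called in the opposite direction, and neither of the 2 other kept probes of Casp4 passed. Of the other kept probes of genes called at least 2-fold lower here, 35.2% moved 2-fold the same way, against 65.4%, 49.0% and 58.4% in the 3 comparisons of sites, and of those called at least 2-fold higher 53.6%, against 57.9%, 76.6% and 76.2%. There were 112 genes above background on all 3 C57BL/6 and on 0 SV129/C57BL/6 arrays, 54 of them called lower, and 122 with the reverse pattern, 66 of them called higher.

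B lymphocyte markers rose in 9 of 16 cases and fell in 0, with 13 rising when adjusted over the list alone (camera adjusted p = 1.56e-13, adjusted p = 0.348 with an estimated correlation): Fcrla was 4.22-fold, the B cell coactivator gene Pou2af1 3.83-fold and Vpreb1 3.31-fold higher. Erythroid markers rose in 7 of 17 cases and fell in 0, or 10 and 1 adjusted over the list alone (camera adjusted p = 3.58e-08, adjusted p = 0.258 with an estimated correlation), among them the carbonic anhydrase gene Car2 (3.98-fold). Of 13 MHC class II and dendritic cell markers Ciita rose (3.04-fold), 0 fell and 6 rose when adjusted over the list alone (camera adjusted p = 0.000355, adjusted p = 0.628 with an estimated correlation). In the interferon list Trim30a fell (at least 9.68-fold), 0 of 28 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.947 with an estimated correlation). Ribosomal protein genes fell in 4 of 60 cases (Rpl29 5.73-fold, Rps4l 3.66-fold, Rps2 and Rps15a) and rose in 0, also adjusted over the list alone (camera adjusted p = 0.0454, adjusted p = 0.947 with an estimated correlation), but their median of -0.08 turned to 0.086 without C57BL/6 replicate 1 and to 0.062 with array weights.

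Single members of lists without a call passed as well. Higher were Olfm4 in the specific granule list (8.01-fold), Cd40 among NF-kB targets (4.65-fold), Nod2 among pattern recognition genes (3.16-fold), Eno1 among glycolysis genes (2.27-fold), Cd3d among T and NK markers (4.53-fold) and Pira2 among Fc, complement and scavenger receptors (4.21-fold). Lower were Ctsc in the azurophil list, Plk1 in the cell cycle list, Fcer1g and Cd300ld among Fc receptors, Casp4 and Casp9 among cell death genes, Naip5 among survival genes (4.25-fold), Jun among immediate early genes (3.12-fold), Itga4 among adhesion molecules, the Rac effector kinase gene Pak1 (4.26-fold) and the basophil protease gene Mcpt8 (2.22-fold). No member passed in the lists of neutrophil identity, gelatinase granule proteins, progenitor genes, chemoattractant receptors, chemokines, cytokines, NADPH oxidase, lipid mediators, hypoxia, respiratory chain, heat shock, macrophage, platelet or mesothelial genes, where the 2-fold self-test recovery of 31% limits what can be said. At an unadjusted limma p under 0.05, 6 members of these 14 lists were higher and 10 lower. Among the genes that did not pass were S100a8 (log2 difference -0.03), S100a9 (0.04) and Csf3r (0.86). In a test adjusted over the list alone, 2 gelatinase granule genes rose, 2 Fc receptor genes rose and 3 fell, and 4 immediate early genes fell, with the other counts the same.

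Of the 32 lists 5 were called, 3 upward and 2 downward, 0 with an estimated correlation (2 at an unadjusted p under 0.05), and 8 without C57BL/6 replicate 1. The median, mean and test differed in sign for 7 lists without a call: cell cycle, cytokines, survival, glycolysis, T and NK lymphocytes, platelets, and eosinophils, basophils and mast cells. Leaving out SV129/C57BL/6 replicate 1 or 2 gave 364 and 363 genes, and under median scaling the median of all genes shifted by 0.13 and 78.2% of calls were higher against 64.0%. The interferon call was lost without C57BL/6 replicate 2 (camera adjusted p = 0.484) or 3 (0.175), with medians of -0.0031 and -0.31 against -0.47, and -1.18 without replicate 1. The ribosomal call was lost without C57BL/6 replicate 1 (0.884) or SV129/C57BL/6 replicate 3 (0.0873), and its median was -0.15 and -0.16 without C57BL/6 replicates 2 and 3. The erythroid median of 1.75 moved to 1.16 without C57BL/6 replicate 2 and that of MHC class II markers from 0.61 to 0.39 without SV129/C57BL/6 replicate 3. Calls were gained without C57BL/6 replicate 1 by azurophil (camera adjusted p = 0.0140), Fc receptor (0.0106), cell death (0.00325) and immediate early genes (0.0200), without its replicate 2 by NADPH oxidase, respiratory chain and immediate early genes (0.0250 each), and without its replicate 3 by gelatinase granule (0.0164) and pattern recognition genes (0.009996). Immediate early genes gained one without SV129/C57BL/6 replicate 1 (0.0488) or 2 (0.0114) or blood replicate 1 (0.0476) or 2 (0.0448), cell death genes without SV129/C57BL/6 replicate 2 (0.0374), azurophil (0.000107), pattern recognition (0.04998) and respiratory chain genes (0.0403) without its replicate 3, and azurophil genes without any 1 blood array (0.0448 to 0.0487).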

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

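The column block, the fit without the 2 arrays that stood apart and the medians with bounds were chosen after the results were seen. Of the 412 calls of named genes 346 passed with the same direction under every alternative that measured them (2 were not measured under 1) and 65 were lost under at least 1, and of the 61 list calls 8 passed under every alternative run for lists and 53 were lost, all of them with an estimated correlation. Changes of sign were counted only where the value was called in either setting. The median of the hypoxia list in exudate against blood turned from 0.32 to -0.048 under median scaling, and that of ribosomal proteins in exudate against marrow from -0.07 to 0.25 under cyclic loess. Ribosomal proteins in the strain comparison turned from -0.083 to 0.062 with array weights, 0.086 without C57BL/6 bone marrow replicate 1 and 0.084 without both arrays that stood apart, and ranged from -0.16 to 0.086 with 1 array left out. The interferon list in blood against marrow turned from 0.23 to -0.51 without C57BL/6 bone marrow replicate 1 and to -0.51 without both arrays, and ranged from -0.51 to 0.60 with 1 array left out. With genes at background in 1 group at their bound, called medians moved from 0.62 to 0.092 for chemokines in blood against marrow, 1.08 to 0.61 for specific granules and 0.32 to 0.14 for hypoxia in exudate against blood, and -1.01 to -0.46 for erythroid markers in exudate against marrow. With SV129/C57BL/6 marrow as the reference Pak1 turned from -1.66 to 0.43 in blood and from -1.03 to 1.06 in exudate. The cause was not tested.

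Counts that moved by over 1.5 times are given as genes for blood against marrow, exudate against blood, exudate against marrow and strain, then genes called at both steps and genes with different steps. An adjusted p under 0.01, stricter by construction, gave 2308, 2865, 2387, 351, 1052 and 2633. Array weights gave 7812 genes in exudate against blood, 1104 in the strain comparison, 3795 at both steps and 6986 with different steps. A 2-fold minimum gave 3097 in exudate against blood and 1352 at both steps, and a fit of only the groups compared, with fewer arrays, 2170 in exudate against marrow. Without both arrays that stood apart there were 1079 genes and 8 lists in the strain comparison, 4111 genes at both steps and 7078 with different steps. With an estimated correlation 0, 3, 5 and 0 lists were called, and in the strain comparison 8 under median scaling and 8 without a filter. The cause was not tested for the array weights and the arrays left out.

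Each array left out in turn gave 2946 to 5096 genes and 13 to 20 lists in blood against marrow, 3245 to 6472 and 21 to 24 in exudate against blood, 2931 to 4731 and 18 to 20 in exudate against marrow, 363 to 741 and 5 to 8 in the strain comparison, 1485 to 3197 genes at both steps and 3112 to 6020 with different steps. Genes rising at both steps ranged from 69 to 162, falling at both from 127 to 292, rising then falling from 904 to 1773 and falling then rising from 378 to 973. The low values beyond 1.5 times came without exudate replicate 1 (3245), SV129/C57BL/6 bone marrow replicates 1 and 2 (364 and 363), blood replicate 2 (1485, 127 and 378), blood replicate 3 (419) and blood replicate 1 (69), and the 8 strain lists without C57BL/6 bone marrow replicate 1. With the replicate number as a block 3705, 4528, 3678 and 558 genes, 16, 22, 18 and 6 lists, 2011 genes at both steps and 4145 with different steps were called. The numbers did not pair the arrays: r of same-number deviations lay between -0.241 and 0.104, over 0.1 in 1 of 18 pairs, and 1 of 12 arrays correlated best with its own number. No beadchip block was run, and 34.7% to 41.8% of probes above background limit what could be tested.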

Other observations

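Apart from the splits of the arrays, all tests and gene families below were chosen after the results were seen. Histone genes, which package newly made DNA and largely lack poly(A) tails when made during replication, fell in 44 of 52 cases between marrow and blood and rose in 0, with 42 and 47 falling under median scaling and cyclic loess. Between blood and exudate 10 rose and 9 fell (2 and 11, and 13 and 9, under these scalings). Between marrow and exudate 35 fell and 0 rose (41 and 27 under the other scalings). Guanylate-binding protein genes, interferon-induced GTPases of cell-autonomous defence, rose in 6 of 6 cases between marrow and exudate under all 3 scalings, with Gbp5 at 6.10 (limma adjusted p = 2.6e-05, above background on 1 of 3 marrow arrays) and Gbp2 at 4.30. Interferon-inducible p200 genes, which include DNA sensors, rose in 7 of 9 cases under all 3 scalings, with Ifi205 at 6.75 (2 of 3 marrow arrays) and Ifi207 at 5.04. Ifi202b was at least 2.47-fold higher in SV129/C57BL/6 marrow (limma adjusted p = 0.000195), above background on 3 of 3 arrays there and on 0 of 3 C57BL/6 marrow arrays. Schlafen genes, regulators of myeloid growth and quiescence, rose in 2 of 3 cases between blood and exudate (3 under both other scalings), Slfn2 by 2.30 and Slfn4, above background on 0 of 3 blood arrays, at least 9.49-fold.

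Lymphocyte and macrophage markers were higher in blood than in marrow. A lower share of neutrophil RNA stays open. The T and NK median exceeded the eosinophil, basophil and mast cell median by 4.11 log2 units (95% bootstrap interval 1.73 to 6.35, 10000 draws). With background genes at their bound the medians were 2.44 and -1.39. Both lists had been seen and other cells need not rise alike, so it is no test. Lymphocyte RNA in blood preparations stays open: 16 of 17 T and NK markers rose (Cd3g 13.13, Thy1 13.04 in blood). This restates the pattern and cannot test it. RNA of resident peritoneal macrophages in the preparations labelled blood is a candidate source, since 5 of 6 further genes of that cell type rose against 2 of 8 blood monocyte genes, while 10 of 10 such genes seen among the top changes, which cannot test it, rose, 8 of them from background on all 3 marrow arrays, Prg4 to 14.39 in blood. Neither a sort nor a purity was given in the sources used here, 4 of the 6 further genes had been seen high on exudate replicate 3, a mixed preparation and a wrong label were not told apart, and a change within blood neutrophils was not tested.

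In the strain comparison 112 genes were above background on all C57BL/6 and on 0 SV129/C57BL/6 arrays, and the 50 of them called at least 2-fold lower were tested. Loss of a cell type is argued against as the cause of the whole set: over markers above background on all C57BL/6 arrays, the lowest median of 8 lists (6 other cell types, progenitors, cell cycle) was -0.21 (T and NK, 95% bootstrap interval -0.38 to 0.13) against -1.71 (-2.30 to -1.38) for the 50 genes at their bound, and 1 of 113 such markers, Plk1, was lost. Platelet and mesothelial markers (2 and 1 above background) and types without a list were not tested. A strain variant under the probe may account for some of the 50 and stays open: 4 of 15 other probes of these genes moved 2-fold the same way (26.7%), against 44.3% of 106 in the comparisons of blood and of exudate with marrow (two-sided Fisher's exact p = 0.267), and 35.2% over all genes called at least 2-fold lower. The criterion set for this test took a p above the threshold as evidence against it, which was wrong, because over 15 probes such a p sets no bound.

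C57BL/6 bone marrow replicate 1 and exudate replicate 3 stood apart from their groups, and the latter was closer to the blood arrays (r = 0.906 to 0.929 across genes) than the other exudate arrays were (0.853 to 0.877), though closest to these (0.951 and 0.957). A shift shared by the first 6 and last 6 columns of the signal table is argued against by the correlations, across genes, between groups of the differences between those columns, of which the highest was 0.0659, and fewer probes above background by 0 of 2 arrays with fewer than both others of their group. Resident macrophage RNA on exudate replicate 3 may contribute and stays open: its macrophage and monocyte markers were higher by a median of 0.746 (95% interval -0.363 to 2.44), with 10 of 20 more than 2-fold higher and 4 more than 2-fold lower. Taken apart, 6 of 6 further resident macrophage genes were higher there (median 2.71) and 0 of 8 blood monocyte genes were (median -2.35), but 4 of those 6 had been seen high on this array, so these genes cannot test it. Its T and NK (9.40 against 8.06 and 8.25), B (8.47 against 7.63 and 7.35) and ribosomal protein medians (14.24 against 13.63 and 13.61) lay towards blood too, so RNA of cells like those in the blood preparations stays open, and no biological explanation was tested, since the labels name no difference within a group.

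For the 10 splits of 6 arrays the share cannot be under 0.05, and the real split and the highest other gave 4071 and 0 genes and 16 and 20 lists in blood against marrow, 4950 and 81 genes and 22 and 23 lists in exudate against blood, 4029 and 109 genes and 18 and 18 lists in exudate against marrow, and 598 and 0 genes and 5 and 17 lists in the strain comparison. As many genes came from 1 split each, and as many lists from 4, 3, 2 and 9 splits, the real one included. Splits with 3 arrays from the first or the last 6 columns of the signal table on 1 side gave 5 lists in blood against marrow, 23 in exudate against blood, 17, 18 and 7 in exudate against marrow (the last with the 109 genes) and 7 in the strain comparison, where 16, 22, 18 and 6 lists were called in the real split with these columns as a block. Over 100 drawn splits of the 9 C57BL/6 arrays only the real 1 gave as many, so chance was unlikely but not excluded. The real 1 had 4536 genes with different steps against at most 3116, and 2281 at both steps against at most 1291.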
